A study of Homo sapiens with 3 samples.

How the data were processed

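Crosslinking and immunoprecipitation followed by sequencing (eCLIP) was used to locate RNA bound by TIA1 in HEK293T cells. HEK293T is an established human embryonic kidney line that carries the SV40 large T antigen. In eCLIP, ultraviolet light joins a protein to the RNA it touches, the protein is immunoprecipitated, and the RNA fragments held by it are sequenced beside a size-matched input that was not immunoprecipitated. Per the labels' protocols, cells were crosslinked with 600 mJ of ultraviolet light, and the libraries were sequenced paired-end. The labels describe 2 immunoprecipitated replicates and 1 input.

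Some labels differ from one another. The antibody field names anti-TIA1 with its catalogue number, while the treatment protocol gives the same catalogue number to an Msi1 antibody; the samples are called TIA1 here, after the titles, the antibody field and the extract protocol. The series' design text calls the replicates technical and the extract protocol calls them biological. The growth protocol writes HEK293 and the cell line field HEK293T. Because the source of the replicates is unclear, a spread between them may be technical.

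Per the submitters' processing notes, cutadapt 1.14 and 1.9.1, STAR 2.4.0i and SAMtools 1.4.1 were used and the genome build was hg19. The role and order of these tools, and the program that called clusters, are not given in the sources used here. The extract protocol names the Yeo laboratory's eCLIP pipeline, and the deposited lists carry marks of duplicate removal, merging of inline barcodes, use of read 2, and compression of overlapping clusters in their names. The authors called clusters per replicate, and also deposited 1 list of reproducible peaks for both replicates together, so 3 lists were used. The input has no file of its own used here and enters only through the authors' fold over input and p-value in those lists.

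Each list gives a position, a strand and the authors' values per interval. The deposited −log10 p-value compares the reads of the interval with the input and stops at a ceiling of 400. The deposited log2 fold is the authors' library-scaled ratio of immunoprecipitated reads to input reads. The lists have no header, so these units were read from the values. At the 21 intervals that all 3 lists share, the log2 fold of the reproducible list was the mean of the replicates' values in 21 and its −log10 p-value was the lower of theirs in 21. At the other peaks the overlapping cluster of the other replicate has other bounds, and over all peaks the listed values of the clusters with the largest overlap gave the mean in 56.8% and the lower −log10 p-value in 71.7%. All scores are the authors' and serve to describe, rank or filter intervals within their list. Positions are given from 1 in the build of the files.

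Depth was recovered from the deposited values. In each replicate the log2 fold took discrete steps set by whole read numbers, with an offset equal to the log2 ratio of the input total to the library total. The smallest whole totals that gave both offsets were multiplied by 1 to 6, and the multiple that best returned the deposited −log10 p-values was kept. At multiple 3 the largest difference was 1.17e-07. The read pair of each interval was then the multiple of its reduced fraction whose p-value matched within a relative tolerance of 2e-05. The p-value was Fisher's exact test where an observed or expected number was under 5 and a chi-square test with Yates' correction otherwise, with −log10 p set to 0 for depleted intervals. That rule was found by trying forms of the test on these data until the p-values matched. Reads were recovered uniquely for 92.4% of the clusters of replicate 1 and 97.1% of those of replicate 2. Intervals at the p-value ceiling have no reads, and an input number of 1 may stand for 0 or 1, since every deposited fold is finite. As a check, 93 intervals were listed with the same bounds in both replicates. Of the 91 recovered in both, 90 had the same input number although each was recovered from its own list.

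An enriched cluster had a log2 fold of at least 3 and a −log10 p-value of at least 3. Overlap meant at least 1 nt on the same strand, found with bedtools 2.31.1. Among clusters of a replicate that overlapped any cluster of the other, Fisher's exact test (two-sided) compared enriched with unenriched ones, with odds ratios and Woolf 95% intervals. The overlap of independent lists was the product of both numbers of enriched clusters divided by the number of clusters overlapping. Because both replicates share 1 input, pairs of overlapping clusters were also simulated 100 times with Poisson reads from a common rate and a common input. At the interval of each reproducible peak, the value of the replicate that supplied the interval was taken from its list and the other from the mean, which assumes that the mean holds at every peak. Reads of both replicates then came out whole within 1e-04 at 2247 of 2253 peaks (99.7%). Replicates were compared over those peaks with a chi-square test against their pooled share, and peak by peak with exact binomial tests (two-sided) and Benjamini-Hochberg adjustment.

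Reproducible peaks per chromosome were compared with 134777 clusters that were enriched in neither replicate and overlapped no enriched cluster or reproducible peak. Clusters of replicate 2 that overlapped any cluster of replicate 1 were left out of this background, so most of it came from replicate 1. The same held for the background limited to clusters with enough reads to pass. Fisher's exact test (two-sided) was run for 24 chromosomes, with Benjamini-Hochberg adjustment. The share of reproducible peaks within 1000 nt of another on the same strand was compared with 10000 random draws of as many clusters of replicate 1, for which the smallest two-sided p is 0.0002. Binomial intervals are exact Clopper-Pearson, and the limit for a count of 0 is 3 counts of the total. Peaks and clusters are not replicates, so p-values over them describe these libraries, and all intervals cover counting error only.

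The regions named are the 10 reproducible peaks with the highest log2 fold, the 10 with the highest −log10 p-value and the 5 stretches of at most 10000 nt on 1 strand with the most peaks. This rule, the cut-offs, the overlap test, the chromosome test and the closeness test were fixed before the data were examined. Added after seeing the data were the recovery of reads, the thinning of replicate 1, the removal of the 5 densest stretches and the counts per 10 kb locus. So were the background and random draws limited to clusters with enough reads to pass, the same draws without enriched clusters and the joining of nearby intervals. The mitochondrial comparison, the sharing of unenriched clusters with enough reads and the tests of reads between replicates were also added then. Enough reads means at least 13 in replicate 1 and 10 in replicate 2, the fewest that pass both cut-offs with an input number of 1. Clusters without unique reads entered this count with the smallest read pair that fitted their fold. Alternatives were stricter and laxer cut-offs, reciprocal overlap, the opposite strand, each replicate alone, and other distances.

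The annotation at hand is of another build, GRCh38, and was not used for positions. In replicate 1, 1925 clusters on 13 chromosomes ended past the last gene of that annotation, and in replicate 2 1096 clusters on 12 chromosomes. Gene names, gene regions, sequence elements, splice sites and gene lists were planned and are not analysed here, because no annotation or sequence of the files' build was used.

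Statistics used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 drew the plots. The steps were tested on simulated data. All 3 made-up totals were recovered exactly. Of 3000 simulated clusters per replicate, 2937 and 2999 were recovered uniquely, and the reads were right in 2935 of 2937 and 2999 of 2999. These simulations used the same form of p-value, so they test the recovery and not that form. With no shared enrichment the overlap test passed 0.05 in 2 of 100 runs. With random peaks, 3 of 2400 chromosome tests were called, and the closeness test passed 0.05 in 3 of 40 runs. With 200 peaks moved to chromosome X that chromosome was called in 100 of 100 runs, and with 200 planted neighbours the closeness test passed in 40 of 40.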

Results

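TIA1 is an RNA-binding protein that attaches to U-rich RNA, takes part in splicing and translation control, and gathers in stress granules. Its RNA contacts in HEK293T cells were mapped by eCLIP in 2 immunoprecipitated replicates against 1 input. The recovered library totals were 2683407 reads in replicate 1, 1997817 reads in replicate 2 and 2851338 reads in the input. Depth limited single clusters. Among clusters whose reads were recovered uniquely, the median was 4 reads in each replicate, and 37.1% in replicate 1 and 41.9% in replicate 2 held 3. Clusters took up 22.9% of the reads of replicate 1 and 20.0% of those of replicate 2, counting clusters whose reads were recovered uniquely.

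The first question was how much RNA in each replicate was enriched over the input. Replicate 1 had 103134 clusters covering 3608627 nt, and replicate 2 had 66222 clusters covering 2185391 nt. Most clusters lay above the input, 94.3% in replicate 1 and 96.0% in replicate 2, with median log2 folds of 1.67 and 2.10. Those medians are also the commonest single value of each list, held by 26.7% and 28.1% of clusters, which is the fold of 3 reads over an input number of 1. At a log2 fold and a −log10 p of at least 3, 3184 clusters (3.09%) of replicate 1 and 3524 clusters (5.32%) of replicate 2 were enriched. At a log2 fold of at least 1 and the same −log10 p the order of the replicates turned, with 4266 clusters in replicate 1 and 4212 in replicate 2.

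Enriched clusters were wider than clusters at large. Their median width was 53 nt in replicate 1 and 50 nt in replicate 2, against 32 nt (interquartile range 25 to 42) and 30 nt (23 to 39) for all clusters. Enriched clusters also need more reads, at least 13 in replicate 1 and 10 in replicate 2, and widths were not compared at matched reads. Their median log2 fold was 3.95 in replicate 1 and 3.97 in replicate 2, on a median of 20.5 and 15 reads. They held at least 3.68% of all reads of replicate 1 and 3.98% of those of replicate 2, leaving out 4 enriched clusters of each at the p-value ceiling, whose reads were not recovered. No test across samples is possible with 1 input and no file of its own used here. In 54.7% of the enriched clusters of replicate 1 and 61.2% of those of replicate 2 the input number was 1, so these folds rest on the smallest input number that occurs.

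The second question was whether the replicates found the same RNA sites. Of the enriched clusters of replicate 1, 3027 of 3184 (95.1%) overlapped some cluster of replicate 2 on the same strand, and 2018 (63.4%) overlapped an enriched one. In the other direction 3350 of 3524 (95.1%) overlapped some cluster of replicate 1 and 2012 (57.1%) an enriched one. Clusters at large were shared less: 28.9% of those of replicate 1 and 45.0% of those of replicate 2 overlapped the other list. Much of that gap goes with read number, since unenriched clusters with enough reads to pass overlapped the other list in 80.8% of 4427 in replicate 1 and 91.2% of 3436 in replicate 2. As a background, 13 clusters of each replicate overlapped a cluster of the other on the opposite strand.

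Among overlapping clusters, enriched ones of replicate 1 met enriched ones of replicate 2 with an odds ratio of 35.0 (95% interval 32.0 to 38.4, Fisher's exact test). The reverse odds ratio was 34.3 (31.3 to 37.6). Independent lists of these sizes would share 352 clusters. Of the 29829 overlapping clusters of replicate 1, however, 3027 were enriched and 3578 were unenriched with enough reads to pass. The rest were counted with too few reads to be enriched. Much of the odds ratio and of the excess over 352 may therefore go with read number, and no comparison at matched reads was made. Simulated replicates with no enrichment and a common input called a mean of 1.76 and 3.37 of 27768 overlapping pairs enriched and 0.08 in both, against 3023, 3428 and 2002 observed. With so few calls that simulation does not show how far a shared input makes enriched clusters coincide, and the input could not be split, so part of the excess over independent lists may come from it.

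The third question was what the authors' reproducible list holds. It had 2253 peaks, 1116 on the plus strand and 1137 on the minus strand, with a median width of 53 nt (interquartile range 44 to 66). Their median log2 fold over input was 4.15, which is 17.8-fold, and the highest was 7.23. The log2 fold lay between 3 and 4 in 891 peaks, between 4 and 5 in 1084, between 5 and 6 in 238, and at 6 or above in 40. The median −log10 p was 4.88, and 4 peaks stood at the ceiling of 400.

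Each reproducible peak had the bounds of a cluster in a replicate list: 1200 of replicate 1 alone, 1032 of replicate 2 alone and 21 of both. An enriched cluster of replicate 1 overlapped 2116 peaks (93.9%) and one of replicate 2 overlapped 2135 (94.8%). Enriched clusters of both replicates overlapped 1998 peaks (88.7%, exact 95% interval 87.3 to 90.0), and no peak lacked both. Conversely, 2016 of the 2018 clusters of replicate 1 that were enriched in both replicates (99.9%) overlapped a listed peak. Every listed peak, however, had a log2 fold and a −log10 p of at least 3, the cut-offs used here for enriched clusters. Its values were read as the mean fold and the lower −log10 p of the same replicates. These overlaps are therefore largely set by the limits of the list and are not independent evidence of reproducibility. At a stricter log2 fold of 4 and −log10 p of 5, 25.3% of the peaks had enriched clusters in both replicates.

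The replicates were then compared within the listed peaks. The median log2 fold was 4.09 in replicate 1 and 4.18 in replicate 2, and 2144 peaks (95.2%) reached 3 in both. The median absolute difference between replicates was 0.29 on the log2 scale and the 90th percentile 0.78, which corresponds to an SD of 0.33 per replicate (n = 2). Both folds of a peak are over the same input reads, so this difference leaves out the error of the input. The peaks held a median of 24 reads in replicate 1 and 20 in replicate 2 over an input number of 1.

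Read numbers at these peaks still differed between replicates by more than counting error. Over 2247 peaks with whole reads, replicate 1 held 56.3% of the reads (exact 95% interval 56.0 to 56.5), against 57.3% of the library totals. The chi-square per degree of freedom against a common share was 1.60 (p = 2.76e-66). The chi-square per degree of freedom was 4.42 over the 292 peaks with at least 100 reads (p = 1.03e-124) and 1.16 over the 1955 peaks with fewer (p = 1.53e-06). Over 91 intervals with the same bounds in both lists, the mean chi-square per interval against the share of the library totals was 1.01. That is another measure than the values against the pooled share of the peaks. It rests on a median of 19 reads, where an excess is hard to see. Most peaks took their bounds from 1 replicate alone (1200 and 1032, against 21 from both). How far such bounds add to the differences was not tested. The libraries were counted as 2 replicates. The list's thresholds were applied to the same values, which narrows the differences that can be seen.

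**Figure D1:**
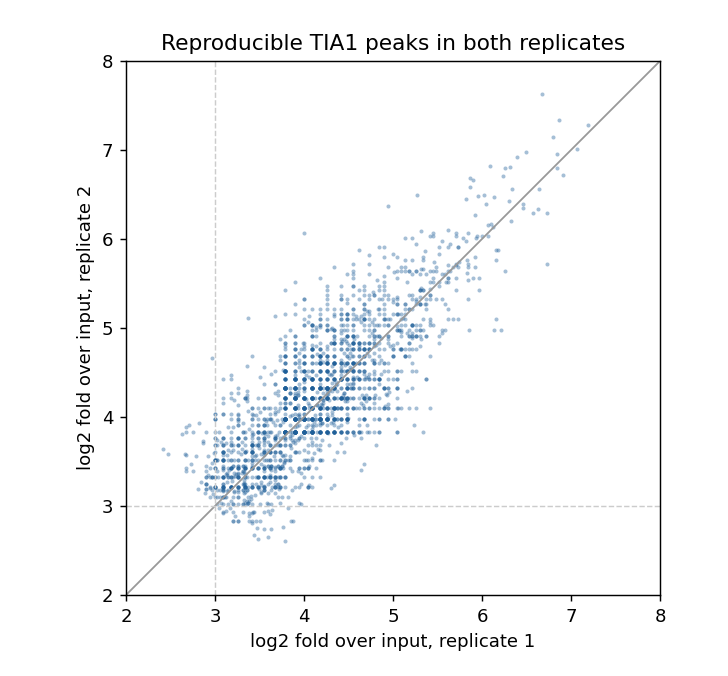
Log2 fold over input of each reproducible TIA1 peak in replicate 1 (horizontal axis) and replicate 2 (vertical axis), 1 point per peak, with equal values along the solid line and a log2 fold of 3 at the dashed lines. Most of the 2253 peaks lie near the line, 2144 of them at 3 or above in both replicates, and the grid of points at low folds comes from small whole read numbers.

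The strongest sites were examined next. The highest log2 fold, 7.23 ± 0.07 (SD, n = 2), was on chromosome 1 from 165697159 to 165697227 on the minus strand, with 137 and 109 reads over an input number of 1. Next came a 16 nt peak on chromosome 7 from 148700594 to 148700609, minus strand, at 7.15 ± 0.68 (SD, n = 2), with 96 reads in replicate 1 and 139 in replicate 2. A peak on chromosome 16 from 18803032 to 18803160, minus strand, reached 7.10 ± 0.33 (SD, n = 2). On the plus strand of chromosome 3, the peak from 39449302 to 39449379 had a log2 fold of 7.04 ± 0.05 (SD, n = 2), with 253 and 180 reads over an input number of 2.

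The other peaks among the 10 with the highest fold ran from 6.97 down to 6.66 on the log2 scale. They lay on chromosome X from 102632788 to 102632924 (plus), chromosome 14 from 73568097 to 73568134 (plus) and chromosome 12 from 50158598 to 50158650 (plus). The rest lay on chromosome 3 from 13358885 to 13358975 (minus), chromosome 22 from 19023828 to 19023897 (minus) and chromosome X from 132669999 to 132670053 (minus). The chromosome 14 peak stood at 6.90 ± 0.08 (SD, n = 2) on 324 and 260 reads over an input number of 3.

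Peaks with the highest −log10 p were partly elsewhere. Of the 10 peaks with the highest −log10 p, 2 were also among the 10 with the highest fold, those at 73568097 on chromosome 14 and 39449302 on chromosome 3. The 4 peaks at the ceiling had lower folds. On the plus strand of chromosome 11 they were those from 65272517 to 65272527 (log2 fold 5.88 ± 0.87, SD, n = 2), from 65272528 to 65272601 (4.41 ± 0.60) and from 65268313 to 65268339 (3.39 ± 0.08). The fourth lay on the minus strand of chromosome X from 73047556 to 73047633 (3.55 ± 0.05). No reads were recovered at these 4 peaks, so replicate values derived from the mean, and their SDs, are unchecked there. At 65272517 the derived value of replicate 2 was 6.49. The highest fold listed for a cluster of replicate 2 from 65268313 to 65272601 was 5.09.

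Below the ceiling, a peak on chromosome X from 73070255 to 73070309, minus strand, had a log2 fold of 4.11 ± 0.13 (SD, n = 2) on 383 and 323 reads over 25 in the input. A peak on chromosome 17 from 56078767 to 56078831, minus strand, had 6.13 in each replicate on 329 and 245 reads over 5. A peak on chromosome 19 from 13054943 to 13054991, plus strand, had 4.47 ± 0.08 on 360 and 290 reads over 18. A further peak on chromosome 11, from 65272218 to 65272243 on the plus strand, had 3.83 ± 0.20 on 365 and 329 reads over 30.

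Reproducible peaks were crowded in some stretches. The densest held 23 reproducible peaks on the plus strand of chromosome 11 from 65192274 to 65202121, with log2 folds from 3.16 to 5.97. Beginning 66.2 kb further along the same strand, 13 peaks lay from 65268313 to 65272601, with log2 folds from 3.29 to 5.88 and 3 of the 4 peaks at the p-value ceiling. The minus strand of chromosome 7 from 26230859 to 26238786 held 10 peaks (3.13 to 5.66). The minus strand of chromosome 17 from 56076836 to 56083030 held 9 (3.21 to 6.13), and the plus strand of chromosome 5 from 179155943 to 179157808 held 9 (3.12 to 5.73).

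These 5 stretches held 64 peaks (2.84%), among them 5 of the 10 peaks with the highest −log10 p and none of the 10 with the highest fold. As they were chosen by reproducible peaks, both replicates had enriched clusters in each. In the densest stretch 27 of 49 clusters of replicate 1 and 28 of 57 of replicate 2 were enriched, and in the other stretch on chromosome 11 11 of 34 and 12 of 34. The enriched clusters were 10 of 16 and 11 of 13 on chromosome 7, 8 of 24 and 11 of 20 on chromosome 17, and 11 of 16 and 9 of 16 on chromosome 5.

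**Figure D2:**
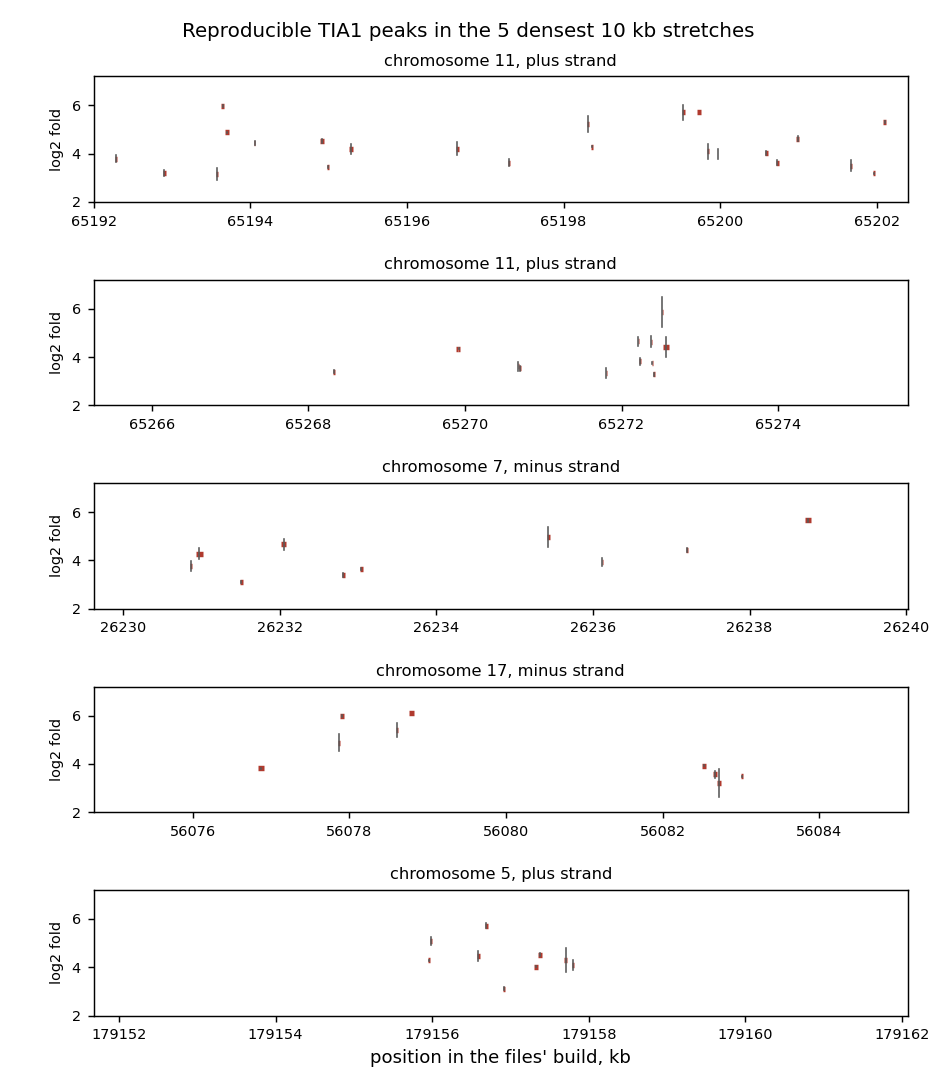
Reproducible TIA1 peaks in the 5 stretches with the most peaks, with the position in kb on the horizontal axis and log2 fold over input on the vertical axis. Each short horizontal bar is a peak at its mean fold and each thin vertical line joins the values of the 2 replicates; the stretches hold 23, 13, 10, 9 and 9 peaks from top to bottom.

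Of the 2253 peaks, 1212 nonetheless had no other within 10000 nt on the same strand. Joined across gaps of up to 10000 nt on the same strand, the peaks formed 1570 loci, of which 1212 (77.2%) held 1 peak, 324 held 2 to 4, and 34 held 5 or more. Those 34 loci contained 259 peaks (11.5%), and the most peaks in a locus was 31. Of all reproducible peaks, 29.1% lay within 1000 nt of another on the same strand. Random draws of as many clusters of replicate 1 gave 3.26% (95% of draws 2.26 to 4.35; permutation p = 0.0002, the smallest the draws can give). Draws of clusters with enough reads to pass, a pool of which 41.8% was enriched, gave 27.5% (25.3 to 29.6; permutation p = 0.135), which ended the call. Against draws of such clusters that were unenriched in both replicates the direction turned, since these gave 38.3% (36.4 to 40.2; permutation p = 0.0002, the smallest possible).

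Across chromosomes, reproducible peaks were more frequent than unenriched clusters on 3 and less frequent on 4 of the 24 tested. Chromosome 11 held 157 peaks, 6.97% against 4.50% of unenriched clusters (odds ratio 1.59, 95% interval 1.35 to 1.87, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 4.09e-06). Chromosome X held 121 peaks, 5.37% against 3.51% (odds ratio 1.56, 1.30 to 1.88, exact test, adjusted p = 7.4e-05). Chromosome 1 held 323 peaks, 14.3% against 11.3% (odds ratio 1.32, 1.17 to 1.49, exact test, adjusted p = 7.4e-05). By the same exact test, peaks were less frequent on chromosomes 9 (odds ratio 0.633, adjusted p = 0.00156), 7 (0.683, adjusted p = 0.00146), 22 (0.709, adjusted p = 0.0319) and 19 (0.743, adjusted p = 0.0236).

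Some of these calls depended on the background. In the same exact test against unenriched clusters with enough reads to pass, chromosome 1 stayed higher (odds ratio 1.24, adjusted p = 0.0209) and 19 lower (0.408, adjusted p = 4.18e-14), X turned lower (0.758, adjusted p = 0.0304), and 4 calls ended, with 9 (1.04) and 11 (1.05) near 1 and 7 (0.823) and 22 (0.739) still below it. That background newly called chromosomes 2 (1.36), 3 (1.63), 6 (1.60) and 12 (1.38) as higher, and 16 (0.562) and the mitochondrial genome (0 peaks against 1.12% of the background) as lower. Counted once per 10 kb locus, 1 and X stayed higher, 18 was newly lower (0.506), and 5 calls ended. Of these, 9 (0.682) and 7 (0.781) were still below 1 and 11 (1.10), 19 (1.10) and 22 (1.05) above it. Both sides were joined, to 1570 loci of peaks and 19789 of unenriched clusters, so a change can come from either. On chromosome 19 the peak share went from 3.86% to 3.82% and the background share from 5.13% to 3.48%. Strand did not separate the sets: 49.5% of the peaks and 51.0% of unenriched clusters lay on the plus strand (odds ratio 0.943, 0.867 to 1.02, Fisher's exact test, p = 0.167).

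**Figure D3:**
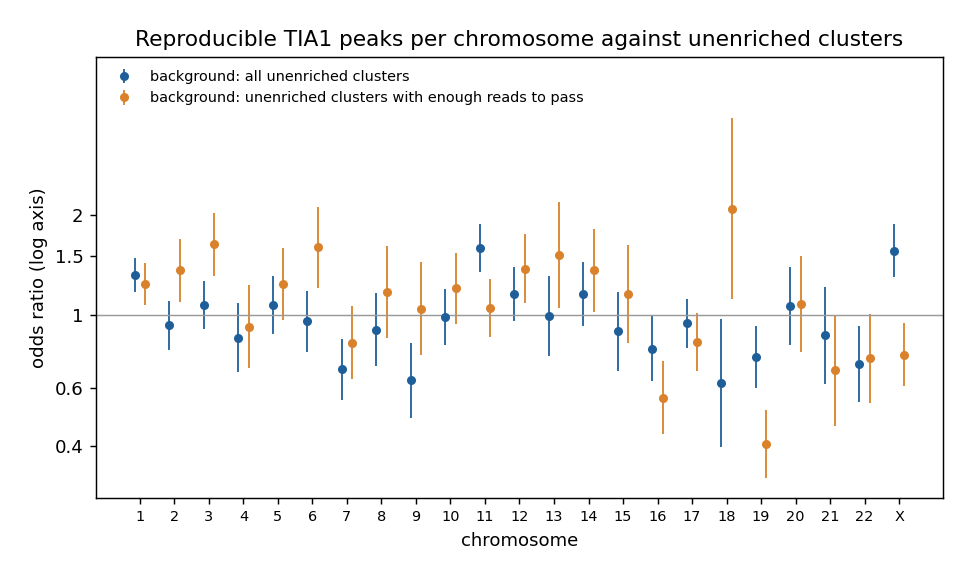
Odds ratio (log axis) of reproducible TIA1 peaks against unenriched clusters on each chromosome, with 95% intervals, for all unenriched clusters (blue) and for those with enough reads to pass (orange). Chromosome X moves from 1.56 to 0.758 between the backgrounds, while chromosome 1 stays above 1 in both; the mitochondrial genome, with 0 peaks, is not drawn.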

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

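The thinning, the limit on reads, the counts per locus, the joined intervals, the draws limited by reads and the removal of dense stretches were chosen after seeing the data, and the other settings before. Of 30 settings of the main results, 19 kept their direction and their side of the threshold, or a count within 1.5 times. For enriched clusters each count was set against that of its own replicate only. At a log2 fold of 1 both were counted as kept (4266 in replicate 1, 4212 in replicate 2), although the order of the replicates turned. For chromosomes called, too, only numbers were compared. Against clusters with enough reads 9 were called instead of 7. Of the 7, 2 kept their call, 1 turned and 4 lost it, and 6 others were new. At a stricter log2 fold of 4 and −log10 p of 5, enriched clusters fell to 914 in replicate 1 and 1001 in replicate 2, chromosomes called to 3, and reproducible peaks with enriched clusters in both replicates to 25.3%. That last share was 95.4% at a laxer log2 fold of 1, 83.0% with reciprocal overlap and 0% on the opposite strand. There the odds ratio of the overlap was 8.33 (0.116 to 596), over 13 clusters with 0.5 added to each cell. Per 10 kb locus 3 chromosomes were called, 2 of the 7 and 1 new. The 29.1% of peaks within 1000 nt of another no longer passed against draws of clusters with enough reads, and lay below such draws without enriched clusters (38.3%). With 1 replicate alone, 7 to 8 chromosomes were called and 28.3% to 28.4% of enriched clusters lay within 1000 nt of another. Of 35 settings of single chromosomes 21 kept their call, 10 lost it on the same side of 1 and 4 crossed 1. Of those 4, X was called in the other direction (0.758) against clusters with enough reads, and 9 there (1.04) and 19 (1.10) and 22 (1.05) per locus were no longer called. Apart from the tests of dense stretches, read depth and split sites given with the other observations, the cause was not tested. Depth limits single clusters, since most folds rest on few reads over an input number of 1. Planned settings on gene regions, U-rich sequence, pentamers, 5' splice sites and gene lists were not run, for want of an annotation and sequence of the build used. No paired analysis was possible because the input has no file of its own used here and the groups share fewer than 2 replicate numbers.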

Other observations

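The mitochondrial comparison, the peak-by-peak comparison of reads, the tests per chromosome and the comparison of thinned counts with replicate 2 were chosen only after the results were seen. The thinning and the settings of dense stretches, loci, enough reads and joined intervals were added after seeing the data but before their own results, and the rest was planned.

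RNA from the mitochondrial genome lay below the input. Its 81 clusters in replicate 1 had a median log2 fold of −1.28 and its 85 clusters in replicate 2 of −1.19, against 1.67 and 2.10 for other clusters. The differences, −2.95 and −3.29, each had p = 1e-05 in a permutation test over clusters (two-sided, 100000 resamples), the smallest it can give. Below the input lay 86.4% of the mitochondrial clusters of replicate 1 and 82.4% of those of replicate 2, against 5.62% and 3.88% of the others, and 0 were enriched. Among clusters with enough reads to pass, the medians were −1.11 over 46 mitochondrial and 2.79 over 7565 other clusters in replicate 1. In replicate 2 they were −1.07 over 48 and 3.10 over 6912. Of these mitochondrial clusters, 80.4% in replicate 1 and 79.2% in replicate 2 lay below the input. There the −log10 p is 0 and does not set the reads, so clusters without unique reads were counted with the smallest read pair that fitted. Deeper clusters below the input can therefore be missing on both sides, and the medians are not matched on reads. No reproducible peak was mitochondrial, and 3 peaks, taken as the limit that a count of 0 allows, would be 0.133% of the list. Of all unenriched clusters 98 (0.0727%) were mitochondrial, a share below that limit. Against them the absence of peaks was not called (Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.623).

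Reads at some peaks parted between the replicates by more than counting error, which separate libraries can do without any difference between the cells. Exact binomial tests against the pooled share of 56.3% called 41 of 2247 peaks (1.82%) after Benjamini-Hochberg adjustment at 0.05, 27 with more reads in replicate 1 than that share and 14 with fewer. The called peaks had a median of 154 reads against 44 over all tested, as the test gains power with reads, and their median difference was 1.08 on the log2 scale. The smallest p belonged to chromosome 22 from 38887941 to 38888014, minus strand, with 107 reads in replicate 1 and 266 in replicate 2 over the same 11 input reads (exact binomial test, adjusted p = 1.75e-23). Chromosome 14 from 70238280 to 70238303, plus strand, went the other way with 370 and 151 reads (exact binomial test, adjusted p = 6.01e-09). So did chromosome 5 from 176729325 to 176729366, minus strand, with 205 and 71 reads. Chromosome 5 from 179048195 to 179048230 and chromosome 3 from 123674825 to 123674872, both minus strand, had 60 against 123 and 58 against 116 reads. These 5 peaks were picked by their p-values after they were seen, and with 1 library per replicate the source of such differences was not tested.

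Replicate 2 had fewer clusters but more enriched clusters than replicate 1 at a log2 fold of 3 and, with 1001 against 914, at the stricter setting; at a log2 fold of 1 the order turned, 4212 against 4266. Thinned to the total of replicate 2, replicate 1 had a mean of 3143.67 enriched clusters (3080 to 3217 over 100 draws), all below the 3524 of replicate 2. This argues against read numbers within the listed clusters as the whole cause. Only listed clusters could be thinned, with their bounds from full depth, so an effect of library depth on the calling of clusters was not tested. The bound set first, fewer than the unthinned 3184, was met by the mean and by 96 of 100 draws, so not beyond their spread. Leaving out the 5 densest stretches decides nothing (3453 against 3117), since they held 71 and 67 enriched clusters against a gap of 340. Counted once per 10 kb locus, replicate 2 was enriched in 2363 loci and replicate 1 in 2199. The exact binomial p was 3.03e-05 over the 847 and 683 loci of 1 replicate alone. This argues against dense stretches as the whole cause, though the gap in loci was smaller than that in clusters. A difference in immunoprecipitation between the replicates or an effect of depth on the calling of clusters may remain, for the pattern at these cut-offs only. No biological explanation was tested, since the replicates belong to 1 group.

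More reproducible peaks than unenriched clusters lay on chromosomes 1, 11 and X. Counted once per 10 kb locus, with peaks and unenriched clusters both joined, 2 of the 3 stayed higher. The odds ratios were 1.49 for chromosome 1 and 1.62 for X, so a few dense stretches of peaks do not account for these. On chromosome 1 the peak share went from 14.3% to 13.8% and the background share from 11.3% to 9.67%. The 1.10 of chromosome 11, whose peak share fell from 6.97% to 5.10%, is what dense stretches could produce. Against background clusters with enough reads to pass, 1 of the 3 stayed higher, which by the bound set first left read depth undecided for the group. Taken singly, chromosome 1 stayed at 1.24, against 1.05 for chromosome 11 and 0.758 for X. An unenriched cluster with enough reads must have an input number above 1, so this background was chosen for input as well as reads. For 11 and X it therefore cannot tell read depth of the background clusters from input level. No biological explanation was tested.

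Reproducible peaks lay closer together than random clusters. Joining intervals within 50 nt left 21.9% within 1000 nt of another, against a mean of 2.74% in random draws. This argues against broad sites split by gaps of at most 50 nt as the whole cause. Before joining, 18.6% of the peaks lay within 200 nt of another, against a mean of 0.897% in random draws. Sites split by gaps wider than 50 nt were not tested. Draws of all clusters with enough reads to pass decide nothing, since 41.8% of that pool of 7611 were enriched clusters themselves; 6.72% of these draws reached the 29.1% of the list. Draws of unenriched clusters with enough reads gave a mean of 38.3%, above the list. Those clusters must have an input number above 1, so these draws cannot tell read depth from input level. Highly transcribed RNA may give such clusters close together whether or not TIA1 binds there, and RNA levels were not analysed here.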
